A study of Mus musculus with 2 samples.

How the data were processed

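Gene expression was measured in kidneys of male C57BL/6 mice, 8 weeks old, 24 h after 30 min of warm bilateral ischemia followed by reperfusion. Per the labels, kidney tissue of 3 wild-type mice (180 mg) made up the WT AKI pool and kidney tissue of 6 EST KO mice (124 mg) made up the EST KO AKI pool, where AKI stands for acute kidney injury. EST is estrogen sulfotransferase, the product of Sult1e1. RNA was extracted with Trizol, per the labels' extract protocol, and biotinylated cRNA was hybridised to an Affymetrix mouse expression array, per the labels' label protocol and the platform annotation. Each pool was measured on 1 array. The labels differ on the tissue of the EST KO pool: the description, source and tissue fields give kidney, and the treatment protocol gives liver for that pool. Kidney was taken as the tissue, and hepatocyte genes were read as a check.

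The values used were the authors' deposited intensity values, 1 per probe set and array, on a linear scale, for 45101 probe sets. From the values themselves, each array had been scaled so that its mean, after the lowest and highest 2% were dropped, was 500.0. The scanner software and the method that summarised probes into probe sets are not given in the sources used here. The sorted values of the arrays differed, so no quantile normalization had been applied before deposit. The array medians were 261.8 in the WT pool and 242.4 in the EST KO pool, within the 10% that had been set as the limit for using the values as deposited, so no further scaling was applied.

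Probe sets were named from GEO's platform annotation. A single gene symbol was given for 34958 probe sets, several for 932 and none for 9211; no gene was named from the last 2 kinds. Symbols were updated through the Entrez ID against a RefSeq gene table of assembly GRCm38.p6, which matched 34754 probe sets. That table was used only for names and for which genes neighbour each other. The named probe sets stood for 18194 genes, and each gene was read from its probe set with the highest mean of both arrays.

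Background was taken, per array, as the 95th percentile of 129 probe sets for gene families that are mostly silent in kidney (olfactory, vomeronasal and taste receptors and keratin-associated proteins). It was 676.1 in the WT pool and 638.3 in the EST KO pool. A total of 10839 probe sets (24.0%) lay above it in the WT pool and 10935 (24.2%) in the EST KO pool. A gene was called measured if it lay above background in at least 1 pool, which held for 7492 genes, and 6118 genes lay above it in both. Values below background were set to the background level before log2 was taken, so that a fold against such a value is a lower bound and is given as "at least". No fold is given where both pools lay below background. A gene above background only in the EST KO pool, but under the WT background level, has no order and is counted neither as higher nor as lower.

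The only comparison the design holds is the EST KO pool against the WT pool. With 1 array per genotype no test between genotypes is possible, and sizes are given without p-values: the number of genes at least 2-fold apart, and the median log2 ratio (EST KO minus WT) of gene lists. Each list with at least 5 measured genes was set against 10000 random lists of the same size, matched on mean level in 20 bins. A list was called apart from random lists when its median lay below percentile 2.5 or above percentile 97.5. Genes of a list are often expressed together, so their median varies more than that of random genes, and the percentile describes these 2 arrays only. Intervals on list medians are 95% bootstrap intervals over member genes (2000 draws) and say how much members differ from each other, not how mice differ. Probe-level error was estimated from the difference between the log2 ratios of the 2 brightest probe sets of a gene, for 1663 genes with 2 probe sets above background in both pools.

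The comparison, its thresholds, the background rule, the 33 gene lists, the rule for named genes and the alternatives were all set before the data were examined. The lists covered tubular injury, nephron segments, other cell types of the kidney, inflammation, metabolism, sulfation and steroid handling, sex-biased kidney genes, stress responses, and other tissues. They held 589 entries, of which 531 matched a gene on the array. The named genes are Sult1e1, the 12 genes with the highest and the 12 with the lowest log2 ratio, and up to 4 measured members of each list with the largest absolute log2 ratio. For the 24 extreme genes, a 2-fold difference was needed, all other probe sets of the gene above background had to go the same way, and names without a known function and sex-chromosome check genes were left out. Havcr1, Lcn2, Slc34a1, Lrp2, Tnfrsf12a, Sox9, Slc7a13, Alb, Sult1d1 and the neighbours and relatives of Sult1e1 and Ugt2b38 fall outside that rule, as do collecting duct genes named with the medulla, and were chosen after their values were seen.

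Alternatives changed a single choice at a time: quantile normalization, centring on the median gene, removal of a loess trend on level (span 0.4), a background at the 75th percentile, no floor, the background level added as a pseudocount, the mean of a gene's probe sets, no probe sets that can read several genes (IDs ending in _x_at or _s_at), a 3-fold threshold, and the mean of a list in place of its median. The calculation was tested on simulated data for the EST KO against WT comparison, with 7129 measured genes and 200 changed genes. It called 42% of genes changed 2-fold, 88% of those changed 3-fold, 96% at 4-fold and 100% at 8-fold, and 1 unchanged gene. A simulated list of 20 genes raised by 0.5 on the log2 scale lay at percentile 100, and 4.0% of 200 unchanged lists were called apart. A probe-level SD of 0.275 put in was recovered as 0.272. The simulated noise was this probe-level error alone, without any spread between mice or pools. Changed genes were drawn from those above background in both pools, and unchanged lists were random genes. These rates therefore test the calculation and are not the error rates of the real comparison. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.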

Results

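Kidneys of wild-type mice and of mice lacking estrogen sulfotransferase (EST), the enzyme that attaches sulfate to estrogens and so inactivates them, were compared 24 h after 30 min of bilateral renal ischemia and reperfusion, a model of acute kidney injury. The question posed by the design is how gene expression in injured male kidney differs with loss of EST. The WT pool held tissue of 3 mice and the EST KO pool tissue of 6, and each pool was read on 1 array of 45101 probe sets. There were no replicate arrays, so the spread between mice is unknown, and the number of arrays limits the precision of every value. Both pools came from injured kidneys, so no value here compares injured with uninjured kidney. Values are linear intensities, given as WT then EST KO, and reached 7331 and 8487 at the 99th percentile of probe sets.

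Sult1e1, the disrupted gene, was read by 1 probe set at 472.7 in the WT pool and 17.2 in the EST KO pool. Both values lay below background (676.1 and 638.3), so no fold is given. Among the 129 probe sets of silent gene families, the WT value stood at percentile 85.3 and the EST KO value at percentile 7.0. With background at the 75th percentile of those probe sets, the WT value lay 1.36-fold above it. Values below background have no order, so they do not check the genotype label. The disrupted part of the gene is also not given in the labels, and a probe set outside it would check nothing. The sex label could not be checked firmly either. Eif2s3y, a Y-linked gene, read 532.0 and 489.7 at its brightest probe set, below background in both pools. Xist, the transcript that silences an X chromosome in females, read 736.1 and 682.3 at its brightest probe set, barely above background in both. Its other probe sets read 60.8 and 11, and 14.8 and 18, below background in both pools.

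The EST KO pool held higher levels of proximal tubule transporter and metabolic genes and lower levels of tubular injury genes than the WT pool. Pdzk1, a scaffold protein of the proximal tubule brush border, was 7.71-fold higher (1070 and 8243), and Slc22a6, the basolateral organic anion transporter OAT1, was 6.11-fold higher (1622 and 9904). The fibrinogen chains Fga (9668 and 1515) and Fgg (4708 and 169.6), which injured tubules are known to express, were 6.38-fold and at least 7.38-fold lower. Across 7492 measured genes, 225 were at least 2-fold higher and 105 at least 2-fold lower in the EST KO pool, together 4.4% of the measured genes. Of the 225, 41 lay below background in the WT pool, and of the 105, 30 lay below background in the EST KO pool. Both counts depended on the treatment of dim values: higher and lower genes numbered 124 and 44 with a pseudocount, and 329 and 200 with no floor.

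Among the 12 genes with the highest ratios, 4 were members of the proximal tubule list: Slc13a3, a dicarboxylate transporter (6.64-fold), Keg1, a kidney-enriched acyltransferase-like gene (6.26-fold), Slc22a6, and Slc13a1, a sulfate transporter (5.15-fold). Pck1, the enzyme that commits carbon to gluconeogenesis, was 6.27-fold higher (701.5 and 4396). Cyp24a1, which inactivates vitamin D, read 218.6 and 4761 and was at least 7.04-fold higher. Ttr, the thyroid hormone and retinol carrier transthyretin, was 6.97-fold higher (1716 and 11957), and all 4 of its probe sets above background went the same way. With the mean of their probe sets in place of the brightest, the log2 ratios were 1.74 for Slc22a6 and 1.89 for Cyp24a1, against 2.61 and a bound of 2.82. A pseudocount, which shrinks ratios that rest on dim values, lowered the ratio by over 1.5 times, to log2 2.35 for Pdzk1, 2.17 for Dnajc12, 1.961 for Slc13a3, 1.87 for Pck1 and Thnsl2, and 1.65 for Nat8f1. The others were Dnajc12, a co-chaperone (7.38-fold), Thnsl2 (6.06-fold), Acy3, an aminoacylase (5.16-fold), and Nat8f1, an acetyltransferase-family gene (5.03-fold).

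**Figure D1:**
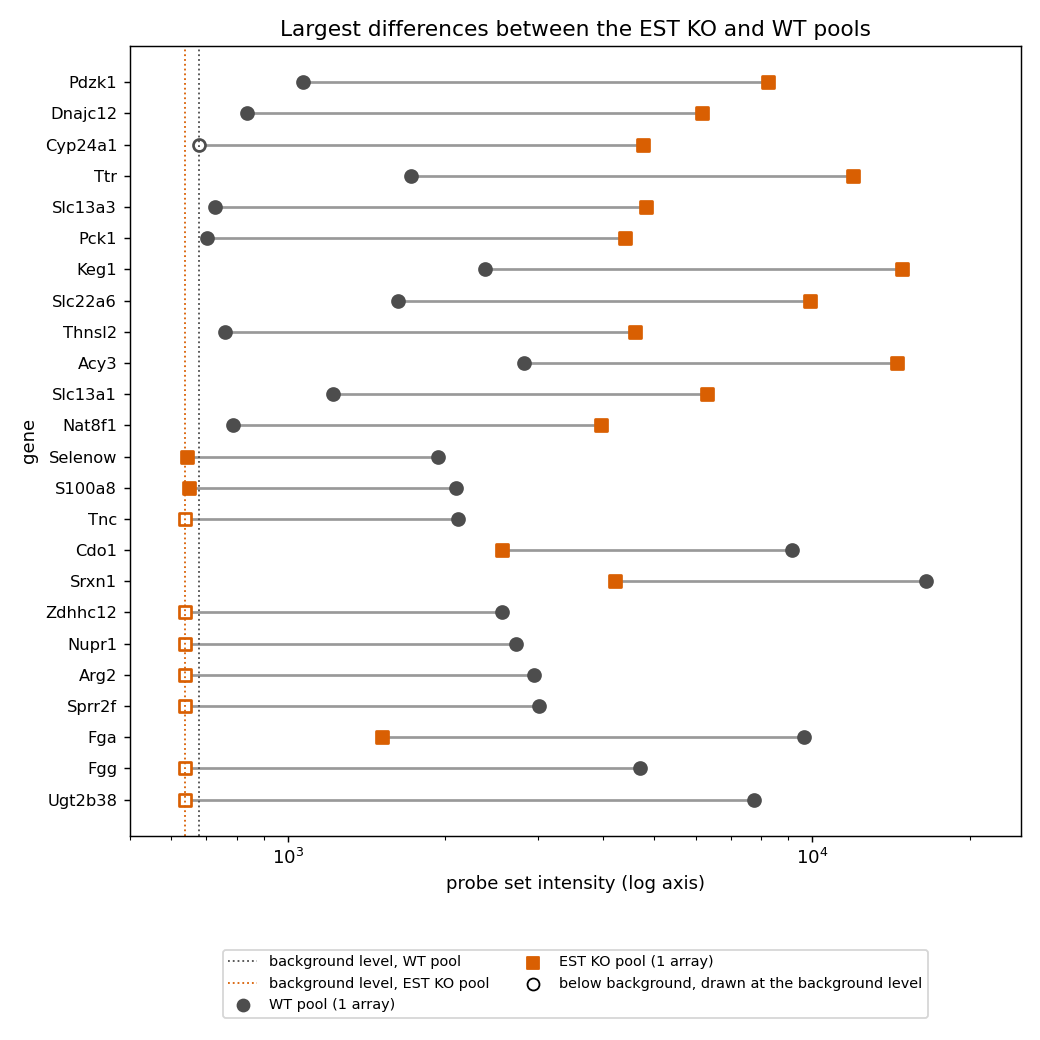
Array intensity (log axis) of the 12 genes with the highest and the 12 with the lowest EST KO to WT ratio, with grey circles for the WT pool and orange squares for the EST KO pool, 1 array each; open symbols are values below background drawn at the background level, and dotted lines mark the background of each array. Ugt2b38 has the widest gap among the lower genes, from 7769 in the WT pool to below background in the EST KO pool, and Pdzk1 the widest among higher genes above background in both pools; gaps that end in an open symbol are lower bounds.

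With dim values held at background, the lowest ratio was that of Ugt2b38, a glucuronosyltransferase of the family that conjugates steroids and drugs, which read 7769 and 130.1 and was at least 12.2-fold lower in the EST KO pool. Sprr2f, a small proline-rich protein, was at least 4.72-fold lower, Arg2, the mitochondrial arginase, at least 4.61-fold lower, and Nupr1, a stress-induced nuclear protein, at least 4.28-fold lower. Srxn1, which reduces hyperoxidised peroxiredoxins, was 3.92-fold lower (16510 and 4207), and Cdo1, which oxidises cysteine, was 3.57-fold lower (9153 and 2565). Zdhhc12 was at least 4.01-fold lower, Tnc, the matrix protein tenascin C, at least 3.31-fold lower, S100a8, a calprotectin subunit abundant in neutrophils, 3.22-fold lower, and Selenow, a selenoprotein, 3.02-fold lower. In the EST KO pool S100a8 (649.3) and Selenow (642.2) lay barely above the background of 638.3. With a pseudocount their log2 ratios were −1.10 and −1.03. Without probe sets that can read several genes, the log2 ratio of Selenow was −0.77, under 2-fold, that of Nupr1 −1.18 and that of Srxn1 −1.29. With the mean of their probe sets, Srxn1 was at −1.21 and Arg2 at −1.26, and Arg2 was at −1.52 with a pseudocount. Ugt2b38, Sprr2f, Cyp4a12a, Hspa1a and Hspa1b have close relatives in the genome, so their probe sets cannot be taken to read those genes alone.

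Of 21 measured tubular injury genes, 19 were lower and 2 higher in the EST KO pool, and 8 were at least 2-fold lower. The list median was −0.65 on the log2 scale (bootstrap interval −1.03 to −0.43), at percentile 0.0 of random lists, whose middle 95% ran from −0.16 to 0.27. Havcr1, which encodes the injury marker KIM-1, read 13344 and 6952 and was 1.92-fold lower. Lcn2, which encodes NGAL, read 35378 and 16994 and was 2.08-fold lower. Krt20, a keratin induced in damaged tubules, was 2.65-fold lower (15736 and 5937). The 2 genes in the other direction were Tnfrsf12a, the TWEAK receptor, 1.54-fold higher (8078 and 12454), and Sox9, a transcription factor of tubule repair, which read 671.2 and 700.0, the former below background.

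Matrix, endothelial and neutrophil genes were lower as groups as well. The fibroblast and matrix list had 11 of 14 measured genes lower, with a median of −0.51 (interval −0.95 to −0.24, percentile 0.0) and 4 genes at least 2-fold lower. These were Tnc, the connective tissue growth factor Ccn2 (2.18-fold), the intermediate filament gene Vim (2.05-fold) and the metalloproteinase inhibitor Timp1 (2.05-fold), although Vim and Timp1 came under 2-fold after centring on the median gene (log2 −0.99 each) and with a pseudocount (−0.80 and −0.66), and Timp1 also under quantile normalization (−0.998) and with the trend removed (−0.94). All 13 measured endothelial genes were lower, with a median of −0.39 (interval −0.62 to −0.22, percentile 0.32) and no member 2-fold apart; Nos3, the endothelial nitric oxide synthase, was at least 1.94-fold lower and Eng, a TGF-beta co-receptor, 1.68-fold lower. All 5 measured neutrophil genes were lower, with a median of −0.51 (interval −1.69 to −0.13, percentile 0.78), led by S100a8; S100a9 was 1.42-fold lower. The neutrophil list was no longer apart from random lists with no floor (percentile 4.84) or with a pseudocount (percentile 5.18). Of 8 measured monocyte and macrophage genes 6 were lower, with a median of −0.29 at percentile 3.12, inside the range of random lists. Cd14, a lipopolysaccharide co-receptor, was 2.11-fold lower (log2 −0.92 with a pseudocount), and Tyrobp, an adaptor of myeloid receptors, 1.88-fold lower. The median of that list left the range of random lists under quantile normalization (−0.28, percentile 1.64). Only 3 genes of T, B and NK cells (median −0.14) and 2 of podocytes (median −0.12) were measured. Ighm was 1.44-fold higher, with its probe sets in disagreement, and Podxl, a podocyte surface protein, 1.34-fold lower.

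Proximal tubule genes were higher in the EST KO pool for 21 of 23 measured members, 9 of them at least 2-fold. The list median was 0.78 (interval 0.60 to 1.32, percentile 100). Slc34a1, the main phosphate transporter of this segment, was 1.68-fold higher (16871 and 28347), and Lrp2, the endocytic receptor megalin, 1.94-fold higher (1787 and 3457). Slc22a7, an organic anion transporter, went the other way and was at least 2.61-fold lower, and Slc7a13 differed by 1.03-fold. The loop of Henle, distal tubule and collecting duct list lay inside the range of random lists, with 7 genes higher, 9 lower and 1 without an order. Its median of −0.13 and its mean of 0.15 differed in sign. Egf, made by the distal tubule, had a log2 ratio of 2.32 (2341 and 11697) and Slc12a1, the loop of Henle salt transporter NKCC2, was 2.29-fold higher, while the collecting duct water channel Aqp2 was 1.57-fold lower.

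**Figure D2:**
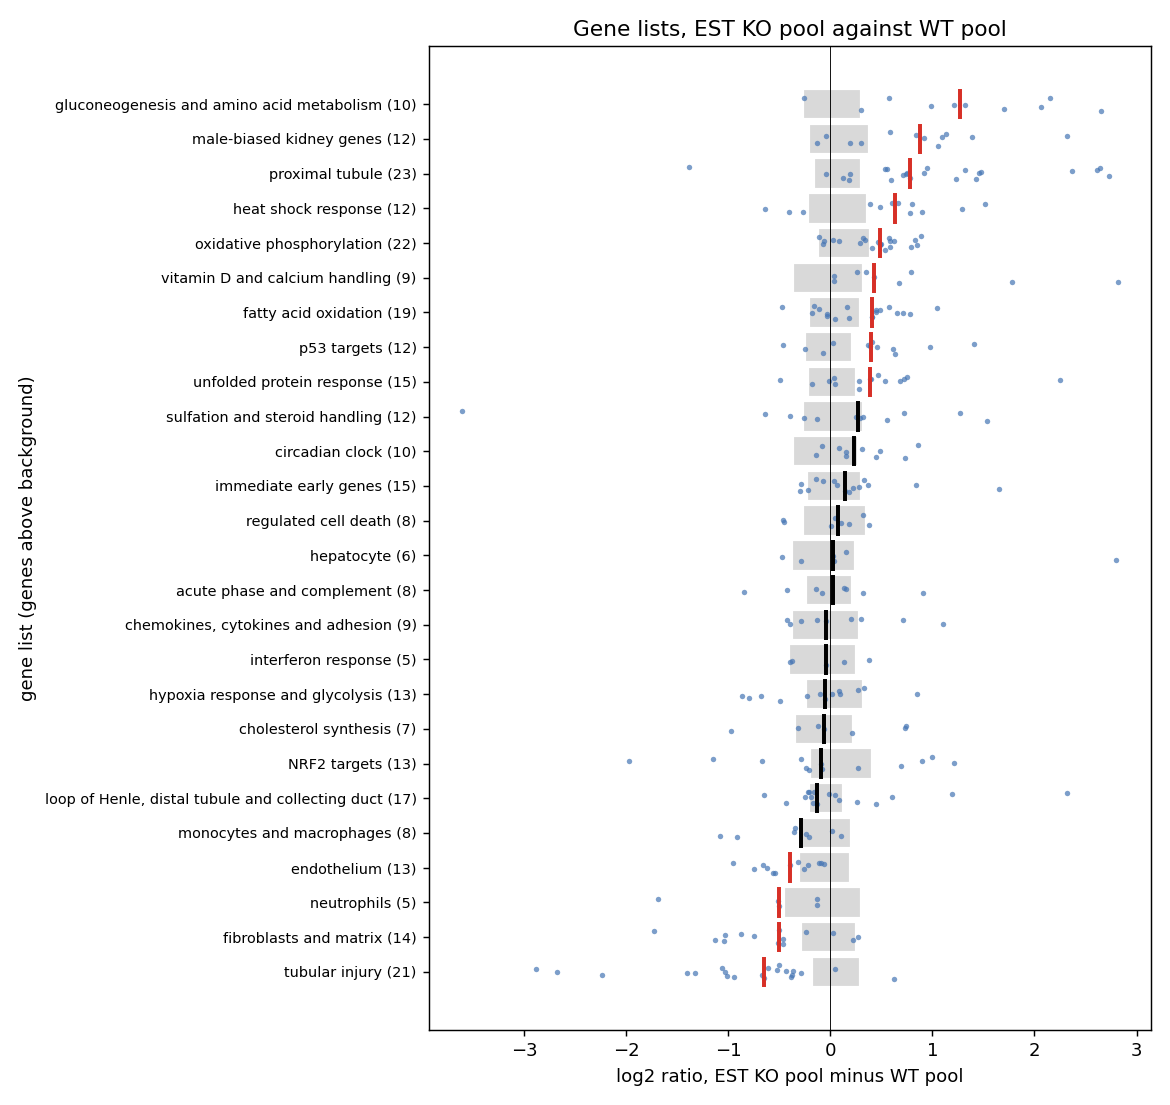
Log2 ratio (EST KO minus WT) of the measured genes of 26 gene lists, each blue point a gene and the number of measured genes in brackets; the vertical bar is the list median, red where it lies outside the middle 95% of 10000 random lists (grey box) and black otherwise. Tubular injury, fibroblast and matrix, endothelial and neutrophil lists lie below that range, and 9 lists, gluconeogenesis and proximal tubule among them, lie above it.

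Metabolic genes of the tubule were higher in the EST KO pool. Gluconeogenesis and amino acid genes were higher for 9 of 10 measured members, 6 of them at least 2-fold, with a median of 1.27 (interval 0.57 to 2.06, percentile 100). Besides Pck1 they included Gldc, the glycine decarboxylase (4.45-fold, log2 1.52 with a pseudocount), Dao, the D-amino acid oxidase (4.18-fold), and Glyat, which conjugates acyl groups to glycine (3.25-fold). Oxidative phosphorylation genes were higher for 19 of 22 members, with a median of 0.49 (interval 0.33 to 0.59, percentile 99.8) and none 2-fold apart; the complex III subunit Uqcrfs1 was 1.85-fold and the complex I subunit Ndufs1 1.80-fold higher. Fatty acid oxidation genes were higher for 13 of 19 members, with a median of 0.41 at percentile 99.9 and an interval of −0.03 to 0.48 that included 0. Pdk4, which restrains glucose oxidation, was 2.06-fold higher (8302 and 17128) and under 2-fold after quantile normalization (log2 0.89), with the trend removed (0.91) and with a pseudocount (0.98), and Ehhadh, a peroxisomal enzyme, 1.64-fold higher. The mean of that list, 0.28, lay inside the range of random lists (percentile 95.3).

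Male-biased and vitamin D genes of the kidney also stood apart. Male-biased kidney genes were higher for 10 of 12 measured members, with a median of 0.88 (interval 0.25 to 1.11, percentile 100). Cyp4a12a, an androgen-induced fatty acid hydroxylase, was 4.97-fold higher (1404 and 6982), Cyp2j13 2.62-fold, and the organic anion transporter Slco1a1 2.19-fold. With a pseudocount Cyp2j13 (log2 0.97) and Slco1a1 (0.84) were under 2-fold. Of the 12, 3 are also in the proximal tubule list, and the other 9 had a median of 1.05. Absence from that list does not place a gene outside the proximal tubule, so the male-biased and proximal tubule shifts cannot be told apart. The female-biased genes measured were Slc22a7 and Cyp4a14, a fatty acid hydroxylase that was 1.71-fold higher. All 9 measured vitamin D and calcium genes were higher, with a median of 0.43 (interval 0.04 to 0.79, percentile 99.7). Cyp24a1 led them, followed by Kl, the FGF23 co-receptor Klotho (3.43-fold), S100g, a calcium-binding protein (1.73-fold), and Vdr, the vitamin D receptor (1.60-fold).

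Sulfation and steroid genes, the family of the disrupted enzyme, did not stand apart as a list. Of 12 measured members 7 were higher and 5 lower, with a median of 0.27 at percentile 96.5 and a mean of −0.01. With the 75th percentile background, which left 17 genes measured, the median was −0.11 (percentile 26.9), so the list has no settled direction. Sult1c2, another sulfotransferase, was at least 2.90-fold higher, Hsd17b11, a steroid dehydrogenase, 2.41-fold higher, and Papss2, which makes the sulfate donor, 1.65-fold higher, against Ugt2b38 in the other direction. Sult1d1, a sulfotransferase next to Sult1e1, was 1.19-fold higher (8122 and 9663).

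Unfolded protein response, heat shock and p53 lists were higher in the EST KO pool, whereas NRF2 targets (median −0.09) and hypoxia and glycolysis genes (median −0.05) lay inside the range of random lists. Unfolded protein response genes were higher for 12 of 15 members and lower for 2 (median 0.39, interval 0.05 to 0.54, percentile 99.9), led by Herpud1, which acts in the degradation of misfolded endoplasmic reticulum proteins (4.75-fold, 1658 and 7871). Hspa5, the chaperone BiP, was 1.65-fold higher at its brightest probe set, with another probe set opposed. Heat shock genes were higher for 9 of 12 members (median 0.63, interval 0.06 to 0.85, percentile 99.95), with the mitochondrial chaperonin Hspe1 2.85-fold and Hspa1a 2.45-fold higher (log2 0.93 with a pseudocount). Targets of p53 were higher for 9 of 12 members (median 0.40, percentile 99.9), although the interval, −0.02 to 0.63, included 0. Trp53inp1, a p53-induced nuclear protein, was 2.65-fold higher (log2 0.88 with the mean of its probe sets), Ccng1, a cyclin, 1.97-fold, and Cdkn1a, the cell cycle inhibitor p21, 1.56-fold.

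No list of inflammatory signal genes stood apart from random lists. The chemokine, cytokine and adhesion list (9 measured, percentile 54.6), the acute phase and complement list (8 measured, percentile 81.8), the interferon list (5 measured, percentile 59.5) and the immediate early list (15 measured, median 0.15, percentile 84.0) lay inside the range of random lists. Medians of the first 3 lay within 0.05 of 0 and changed sign with the scaling or the handling of dim values. Their intervals were wide (−0.40 to 0.71, −0.42 to 0.32 and −0.39 to 0.38), so a moderate shift either way is not excluded. Single members still differed. Cxcl1, a neutrophil chemoattractant, was 2.16-fold higher in the EST KO pool (2964 and 6388), with log2 ratios from 0.94 under quantile normalization and 0.95 with a pseudocount to 2.16 without probe sets that can read several genes. Icam1, a leukocyte adhesion molecule, was at least 1.64-fold higher. Atf3, a stress-induced transcription factor, read 260.2 and 2133 and was at least 3.16-fold higher. Cfb, a complement factor, was 1.88-fold higher, whereas Cp, ceruloplasmin, was 1.80-fold lower.

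Genes of other tissues were read because of the conflicting tissue label. The hepatocyte list had 6 measured genes with a median of 0.03 at percentile 74.9, and Ttr was its only member 2-fold apart. Alb, serum albumin, among the most abundant liver transcripts, lay below background in both pools (487.9 and 522.3). Adipocyte genes (3 measured, median 0.04) included Lpl, lipoprotein lipase, 1.53-fold higher. Among 3 adrenal genes (median −0.04), Dbh, a catecholamine enzyme, was at least 2.17-fold lower, with its probe sets in disagreement (log2 −0.46 with their mean, −0.77 with a pseudocount). The only red blood cell gene measured, Slc25a37, was 1.14-fold lower. As a sign of RNA quality, the ratio of the 3' to the 5' control probe set was 1.35 in the WT pool and 1.28 in the EST KO pool for actin, and 0.88 and 0.84 for GAPDH.

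The error that 1 array per genotype allows to be measured is that between probe sets of a gene. Its SD on a log2 ratio was 0.28 over 1663 genes, so a single log2 ratio carries a 95% margin of ± 0.54 from this source alone. Over all genes above background in both pools the SD of the log2 ratio was 0.46 and the median −0.05, and the arrays correlated at r = 0.899 across 6118 genes, which are not independent replicates. Of 80 genes at least 2-fold apart that had a further probe set above background in both pools, 72 went the same way in it and 38 were also 2-fold apart.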

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

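The results here come from probe sets outside the gene comparison and from the tissue check. The test of liver tissue was chosen before its result was seen.

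Probe sets with no single gene name were left out of the comparison of genes, and some of them still carried a signal that differed between the pools. Apart from 51 array control probe sets there were 10092 of them, of which 1501 lay above background in at least 1 pool; 37 of these were at least 2-fold higher and 17 at least 2-fold lower in the EST KO pool. That is 3.6% of the 1501, against 4.69% of the 10673 named probe sets above background.

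Ttr was 6.97-fold higher in the EST KO pool, and the treatment protocol names liver for that pool, so liver tissue in it is a candidate explanation. Liver would bring all its abundant transcripts, but the median log2 ratio of the 6 measured hepatocyte genes was 0.027 and Alb lay below background in both pools. Proximal tubule genes were higher, not lower, in the same pool. These values argue against liver as the tissue of the EST KO pool, and against a share of liver large enough to set the level of Ttr. The source of the Ttr signal stays open, and expression in the tubule itself was not tested.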

How the results depend on the processing

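All alternatives were planned, and none reversed a list that stood apart or a named gene 2-fold apart. Of 207 alternative list values, 194 kept their call. A further 26, under centring, are not counted, since a common shift cannot move a percentile. Quantile normalization and trend removal move a list and its level-matched random lists largely together, so calls kept there say little. Monocyte and macrophage genes came to stand apart under quantile normalization (−0.28), with the trend removed (−0.24), without _x_at and _s_at probe sets (−0.33) and as a list mean (−0.38). Circadian genes did so with the 75th percentile background (0.16), no floor (0.24), a pseudocount (0.16) and as a mean (0.30). Sulfation genes did so with the mean of probe sets (0.31) but turned sign with the 75th percentile background (−0.11). Hepatocyte genes came to stand apart as a mean (0.37), to which Ttr contributes most. Neutrophil genes no longer stood apart with no floor (−0.51) or a pseudocount (−0.32), nor did fatty acid oxidation genes as a mean (0.28). The cause was not tested.

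Higher genes numbered 124 with a pseudocount and 57 at 3-fold, against 225. Lower genes numbered 197 with the 75th percentile background, 200 with no floor, 44 with a pseudocount and 14 at 3-fold, against 105. The share of higher genes, 68.2%, ran from 61.6% to 74.5% over the 8 settings at 2-fold. For Sult1e1, the WT value over background became 1.36 with the 75th percentile; settings that act on a ratio were not run, since no fold is given. Of 414 alternative values of the 52 named genes 2-fold apart, 392 stayed 2-fold. The other 22 values, 11 of them under the pseudocount, belonged to 13 genes: Selenow, Cd14, Vim, Timp1, Dbh, Cxcl1, Pdk4, Cyp2j13, Slco1a1, Acsm3, Osgin1, Hspa1a and Trp53inp1. The neutrophil list had under 5 genes without _s_at probe sets and got no value, and centring cannot alter the agreement of probe sets, whose SD ran from 0.20 to 0.32. Signal over background limits the lower genes: 30 of 105 rest on a bound.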

Other observations

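Tests of array scaling, of the proximal tubule and medulla shares and of the Ugt2 family were chosen only after the result was seen; the test of genes near Sult1e1 was chosen before.

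Antioxidant genes under NRF2, a regulator of the response to oxidants, split in direction. Of 13 measured, 5 were higher and 8 lower in the EST KO pool, with a median of −0.09, inside the range of random lists. Srxn1 was 3.92-fold lower at its brightest probe set (log2 −1.29 without probe sets that can read several genes) and Gclc, a subunit of the enzyme that limits glutathione synthesis, 2.21-fold lower (11612 and 5247). Hmox1, heme oxygenase 1, was higher in the EST KO pool (4967 and 9930) and Osgin1 was at least 2.31-fold higher (log2 0.93 with a pseudocount). Hypoxia and glycolysis genes (13 measured, percentile 31.3) also went both ways. Hk1, a hexokinase, was 1.82-fold lower, Pdk1, which restrains pyruvate oxidation, 1.73-fold lower and Pkm, pyruvate kinase, 1.60-fold lower, while Bnip3, a mitophagy receptor, was 1.80-fold higher.

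Circadian clock genes were higher for 8 of 10 measured members, with a median of 0.24 at percentile 96.7, just inside the range of random lists. Dbp, a clock output transcription factor, was 1.81-fold higher, Nr1d1, which encodes REV-ERB alpha, at least 1.66-fold and Nr1d2 1.36-fold. The hour at which kidneys were taken is not given in the sources used here. Cholesterol synthesis genes (7 measured, percentile 57.9) had Hmgcs1 1.66-fold higher and Fdft1, squalene synthase, lower, with a log2 ratio of −0.97 against the background level. Only 4 cell cycle genes were measured, with a median of −0.13 and Pcna, a replication clamp, 1.19-fold lower. Regulated cell death genes (8 measured, percentile 70.5) had Gpx4, which removes lipid peroxides, 1.30-fold higher and Bcl2l1, a survival factor, 1.37-fold lower.

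Tubular injury genes were lower and proximal tubule genes higher in the EST KO pool. Array scaling or a brightness trend as the whole source is argued against, since both lists stayed apart from random lists in the same direction in 2 of 2 settings (quantile normalization and trend removal) and the median gene differed by −0.05, and so is a larger share of proximal tubule RNA alone, since the injury median lay below that of the other nephron segments (difference −0.52, interval −1.10 to −0.28). A smaller share of medulla in the EST KO pool also stays open. The 13 collecting duct and inner medulla genes had a median of −0.25 (interval −0.54 to −0.02), 9 of them lower and 1 without an order. The largest differences were those of Slc14a2, a urea transporter, at least 2.92-fold lower, and Slc5a3, an inositol transporter, 2.67-fold lower. The others were higher, by up to 1.22-fold for Hsd11b2, or lower by less. Milder injury in the EST KO mice, through the genotype or through differences between the 3 and 6 mice in the ischemia they underwent, may underlie the pattern, and 1 array per genotype cannot separate these. The unfolded protein response (0.39), heat shock (0.63) and p53 (0.40) lists stood above random lists in the EST KO pool, the p53 list with an interval that included 0. Without uninjured kidney, it is unknown whether these lists rise with injury here, so they do not decide whether injury was milder.

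With dim values held at background Ugt2b38 had the lowest ratio of the named genes, and it is separated from Sult1e1 by 1 measured gene, Sult1d1, in assembly GRCm38.p6. Of 37 measured genes within 10 Mb of Sult1e1, 4 were 2-fold apart (10.8%, against 4.41% of 7483 placed genes): Ugt2b38, Slc4a4, a bicarbonate transporter (log2 ratio 1.32), Pf4, a platelet chemokine (2.01-fold lower), and Cxcl1. Slc4a4 is also in the proximal tubule list, which was higher as a group, and Pf4 lay at the threshold. Cxcl1 was under 2-fold with quantile normalization (log2 0.94) and a pseudocount (0.95), though further apart without probe sets that can read several genes (2.16). The count of 4 stood at percentile 94.2 of 6688 runs of as many neighbouring genes. By the rule set beforehand, that percentile counted against DNA of the embryonic stem cell strain carried along with the disrupted gene. A single gene more or less would put the count at 98.3 or 85.1, so the outcome rests on 1 gene and the test cannot tell such DNA from chance. The strain is not given in the sources used here. The 2 other measured members of the Ugt2 family had a median of −0.02 (Ugt2b36 0.23, Ugt2b37 −0.27). Ugt2b36 read 693.7 in the WT pool, close to the background of 676.1, and could hardly have shown a loss. Ugt2b37 (2531 and 2103) alone thus shows that it did not share the loss of Ugt2b38. Whether the rest of the family did cannot be told. An effect of the disruption on Ugt2b38 itself was not tested.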
